A study of Mus musculus with 10 samples.

How the data were processed

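Genomic DNA came from sorted spleen cells of mice. Expanded CD45.2+ T cells lacking TET2 and TET3 were sequenced after 1 transfer (3 libraries) or 2 serial transfers (4 libraries) into congenic CD45.1+ recipients, and sorted wild-type CD4 cells (3 samples) served as controls. Per the labels' protocols, the libraries were made with a PCR-free kit and read as paired ends of 150 bases. Per the submitters' processing notes, reads were trimmed with fastp 0.21.0 and aligned with Bowtie2 2.4.5 to mm10. The tool that called copy number is not given in the sources used here, and the column layout of the files is that of CNVkit.

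For each of the 7 mutant libraries, the authors deposited a table of 52941 genomic bins with a median size of 49991 bases and a table of segments. In both tables the deposited log2 value is the coverage of the library over that of a pooled reference, centred by the authors' tool, per the file headers and the values. The deposited depth column is an average read depth per base, a coverage signal that is not normalized. The deposited weight of a bin is a score between 0 and 1, and the number of bins in a segment is a whole-number count, per the file headers. The pooled reference is a single deposited table that names no library, is taken here to pool the 3 controls, and gives for each bin a log2 coverage, a depth, the GC fraction, per the file headers, and a spread between its libraries. Single control libraries were not analysed here, so no spread between controls enters any test. Gene positions came from a RefSeq table of assembly GRCm38.p6, whose primary chromosomes are those of mm10.

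Median autosomal depth was 0.876 to 1.28 per base in the 7 libraries and 0.887 in the reference. The spread of adjacent bins was 0.13 to 0.15 on the log2 scale, which gives an error of 0.029 to 0.034 for the mean of a 1 Mb window. Copies per cell were computed as 2 times the linear ratio, which takes the authors' centring as 2 copies and averages over all cells in the sort. For the receptor loci and the sex chromosomes, copies were computed without division by the reference, so that the reference's own value could be set beside them.

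Before averaging, every pair of libraries was compared by the variance of their 1 Mb window differences against the variance that bin noise gives. The ratio was 1.00 for second transfer BR3 and BR4 and 3.26 to 36.3 for the other 20 pairs. These libraries were therefore averaged and counted as 1 sample, which leaves 6 samples, 3 in each group. This departs from the plan, which had 7 separate samples, and was decided after the data were seen. The counts, differences and tests for which alternatives were run were also computed with 7 libraries counted separately, but the gene test and the profile correlations were not. The labels do not say which first transfer library gave rise to which second transfer library, and the tests treat samples of the 2 transfers as independent.

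A segment was called altered at a log2 of at least 0.2 or at most -0.25 with at least 10 bins. Weighted means of bins were taken over autosomes and over 2403 windows of 1 Mb holding at least 10 bins. Departures from the reference and differences between transfers were tested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Receptor loci, Tet genes and gene lists were tested with exact two-sided sign-flip tests over 6 samples, whose smallest p is 0.03125. Differences between transfers in single values were tested with exact two-sided permutation tests over 20 ordered splits, whose smallest p is 0.1, so they cannot pass 0.05. A test against the reference leaves out the reference's own error, which all libraries share. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples. A limma test of 20541 protein-coding autosomal genes, each by the bins it overlaps, was added after the plan was fixed.

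Sharing of altered segments was compared with 10000 random rotations of each sample's autosomes. The correlation that a shared reference alone gives was simulated with 50 references of 3 libraries, a number assumed from the labelled controls. Gene lists were compared with 10000 circular shifts of the genome-wide gene profile. The lists, the altered-segment bounds and the rule for naming genes were set before the data were examined. The rule names Tet1, Tet2 and Tet3, the 6 antigen receptor loci, every autosome past the threshold (up to 6 in each direction), and list genes in gained or lost segments in at least 2 libraries (up to 15 for each group and for both together). It also names the 10 most extreme segments outside the antigen receptor loci, the 5 strongest windows, taken by p, in each direction of a window test with calls, and the largest altered segment of each library. A gene that the rule names is not reported here.

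The window tests were checked on simulated libraries, with 67 of 2403 windows changed at each size. Noise was drawn independently for each window, at each library's window SD on autosomes without gains. The spread between samples that gained chromosomes add, and the correlation of neighbouring windows, were left out. Against the reference, 89.6% of windows shifted by 0.1 and 100% of those shifted by 0.2 and by 0.5 were recovered, with 25 false calls among 2202 unchanged windows. Between transfers, 23.9%, 98.5% and 100% were recovered at 0.1, 0.2 and 0.5, with 4 false calls. These rates do not hold where gains vary between samples of a group. In the real data chromosome 2 differed by -0.27 between transfers, and 0 windows passed. The autosome test recovered 3 of 3 changed autosomes. Its simulated spread between samples was well below the SD of 0.18 on chromosome 2 and 0.23 on chromosome 15.

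The alternatives were other bounds and segment lengths, recentring on the mode of each library, unweighted medians, 5 Mb windows, estimated library weights, removal of low-weight bins, the exact sign-flip test in place of limma, a replicate block, the 4 libraries that share a name prefix, and each library left out in turn. Added after the data were seen were 7 separate libraries, joined neighbouring segments, receptor loci on a linear scale, and shuffling of whole chromosomes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.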

Results

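The series measured DNA copy number by low-depth whole-genome sequencing in T cells without TET2 and TET3, enzymes that oxidise 5-methylcytosine. The cells had expanded in unirradiated recipients for 16 weeks after a first transfer, or had been moved on to a second recipient, where expansion was seen within 2 to 4 weeks. There were 3 libraries after the first transfer (BR1 to BR3), 4 after the second (BR1 to BR4) and 3 wild-type control samples. The deposited pooled reference names no library and is taken here to be the pool of these controls. Median autosomal depth was 0.996, 1.12 and 0.876 in first transfer BR1 to BR3 and 1.24, 1.02, 1.28 and 1.19 in second transfer BR1 to BR4. Second transfer BR3 and BR4 differed by about the sampling noise (variance ratio 1.00) and were counted as 1 sample, so n = 6 below unless libraries are named. Coordinates are mm10.

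The targeted genes come first, as a check of the genotype label. Relative to its own chromosome, Tet2 was at a log2 of 0.015, -0.0035 and 0.013 in first transfer BR1 to BR3 and 0.11, 0.034, -0.098 and -0.25 in second transfer BR1 to BR4. Tet3 was at -0.058, 0.043 and -0.12 in first transfer BR1 to BR3 and -0.10, 0.0056, 0.10 and -0.033 in second transfer BR1 to BR4. The means were -0.0013 ± 0.092 for Tet2, -0.033 ± 0.071 for Tet3 and 0.0087 ± 0.053 for the untargeted Tet1, and none passed (SD, n = 6, exact sign-flip adjusted p from 0.94 to 0.97). The bin of Tet3 from 83377685 to 83427671 on chromosome 6 was lower in 6 of 6 samples, at -0.14 ± 0.10 (exact sign-flip p = 0.031, adjusted 0.19). The bins are larger than an exon and the deleted part of each gene is not given in the labels, so these values do not check the genotype.

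The main question was which chromosomes departed from wild-type copy number. Chromosome 17 was gained in all 7 libraries, with a mean log2 ratio of 0.55 ± 0.066 (SD, n = 6) and 2.74 to 3.15 copies per cell (limma adjusted p = 2.1e-05). Chromosome 15 had a mean of 0.27 ± 0.23 (SD, n = 6, limma adjusted p = 0.041, higher in 5 of 6 samples), with 2.91 copies in first transfer BR3, 2.62 in second transfer BR1 and 2.80 in second transfer BR2, against 1.99 to 2.26 in the other libraries. First transfer BR3 and second transfer BR1 and BR2 also shared X and Y copies and receptor bins, described below, and might share an origin. The test counts them as independent samples. Chromosome 2 had a mean of 0.21 ± 0.18 (SD, n = 6, limma adjusted p = 0.041, higher in 6 of 6 samples), with 2.69 copies in first transfer BR2 and 2.67 in first transfer BR3. Chromosome 16 did not pass, at 0.21 ± 0.21 (SD, n = 6, limma adjusted p = 0.060), although first transfer BR3 carried 2.89 copies, second transfer BR1 2.51 and first transfer BR1 2.42. Chromosome 6 was at 2.91 copies in second transfer BR3 and BR4 and at 1.96 to 1.99 in the other libraries, and chromosome 14 was at 2.39 copies in first transfer BR3.

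In all, 11 of 19 autosomes passed limma's test, 3 higher and 8 lower. The 8 lower ones moved little. Of these, the 6 with the largest means were chromosomes 8 (-0.022), 4 (-0.020), 7 (-0.015), 13 (-0.013), 12 (-0.0087) and 18 (-0.0065). Chromosome 13 was not lower with unweighted medians, at 0.0039 (limma adjusted p = 0.25), so its call does not show a lower whole chromosome. It holds a small region, described below, at -1.93 ± 0.11 against its flanks (SD, n = 6). The call on chromosome 17 held whichever library was left out, with an adjusted p of at most 0.00036. The call on chromosome 2 ended without any 1 of first transfer BR1, BR2 or BR3 or second transfer BR1 or BR2 (adjusted p up to 0.085), that on chromosome 7 without second transfer BR2 (0.053), and that on chromosome 15 without first transfer BR2 or BR3 or second transfer BR1 or BR2 (up to 0.11). With exact sign-flip tests in place of limma 0 autosomes passed (smallest adjusted p = 0.054), and with unweighted medians 3 passed, chromosomes 17, 8 and 4. Chromosomes 2 and 15 did not pass with unweighted medians (limma adjusted p = 0.063 for both).

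**Figure D1:**
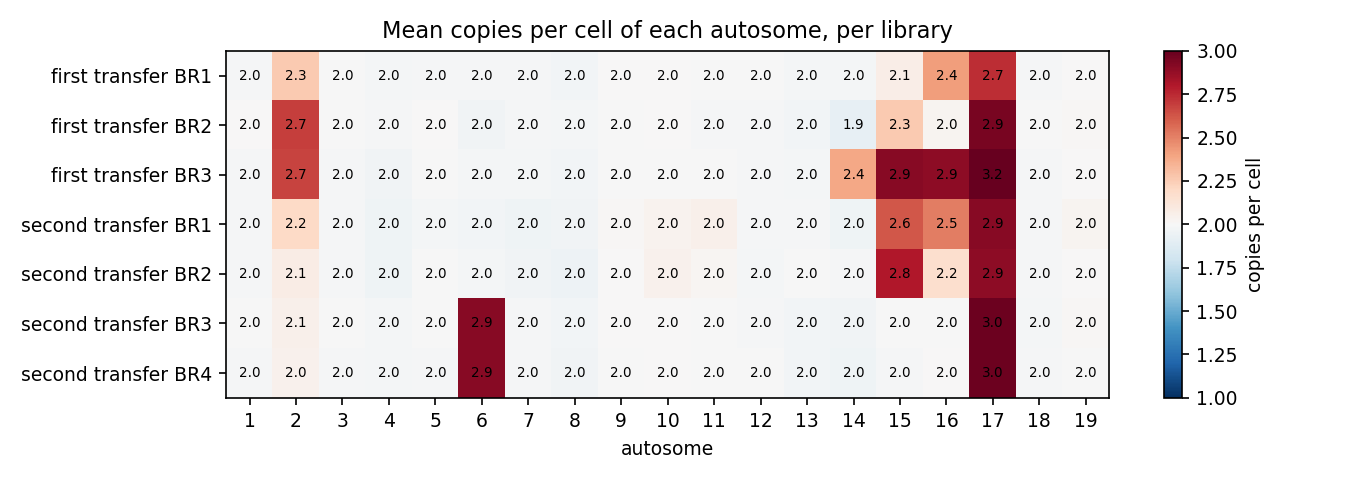
Mean copies per cell (colour and printed value) of the 19 autosomes (columns) in the 7 libraries, with 2 copies taken as the authors' centre and the colour scale ending at 3. Chromosome 17 lies between 2.74 and 3.15 copies in every library, and chromosome 6 stands at 2.91 in second transfer BR3 and BR4.

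At a finer scale, 334 of 2403 windows of 1 Mb departed from the reference in limma's test, 204 higher and 130 lower. Of the windows higher by at least 0.2, all 92 windows of chromosome 17 were among 138, and chromosome 2 gave 38. The 5 higher windows with the smallest p lay on chromosome 17, from 28001550 to 29001335 (0.56), 65043642 to 66043428 (0.57), 52046417 to 53046202 (0.64), 22002830 to 23002616 (0.57) and 59044923 to 60044708 (0.58). The window at 28001550 holds Anks1 and Ppard, and that at 65043642 holds Vapa. Lower windows were mostly slight, with a median of -0.067. Only 4 were at or below -0.25, 2 on chromosome 13 and 2 on chromosome 14. Window SDs within a library were of the size of that median, at 0.035 to 0.072 on autosomes without gains. False calls against the reference also exceeded the threshold in the simulation, so slight windows are uncertain 1 by 1. The 5 lower windows with the smallest p leave out the one on chromosome 14 from 26001732 to 27001422 (-0.33). They began with those on chromosome 13 from 65004754 to 66004493 (-0.63) and from 66004494 to 67004234 (-0.90). These windows on chromosome 13 hold the zinc finger genes Zfp369 and Zfp640. Both genes lie outside the region from 65704572 to 66504363, which was at -1.93 ± 0.11 against its flanks (SD, n = 6). That region holds Gm10324 and 2410141K09Rik. Chromosome 14 from 69014385 to 70014167, which holds Entpd4, was at -0.43, chromosome 8 from 11001490 to 12001675, with Col4a1 and Irs2, at -0.12, and chromosome 4 from 42036287 to 43036914, with Ccl21b and Ccl19, at -0.11. These 5 higher and 5 lower windows went the same way in 6 of 6 samples, with limma adjusted p of 0.0022 or less. The count of windows past the threshold was 143, 200 and 164 without first transfer BR1, BR2 or BR3, and 121 and 149 without second transfer BR1 or BR2. It was 531 (214 higher, 317 lower) after recentring on the mode of each library, which turned the balance of directions, and 225 (160 higher, 65 lower) with unweighted medians.

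The second question was how much of the genome was altered, and whether a second transfer added to it. Altered segments covered 7.89%, 11.3% and 23.7% of the autosomes in first transfer BR1, BR2 and BR3, and 12.2%, 8.29%, 9.97% and 9.95% in second transfer BR1 to BR4. Nearly all of this was gain, and lost segments covered at most 0.190% in any library. In every library the lost segments include the region of chromosome 13 from 65704572 to 66504363, which is not shown to have changed after transfer. The mean altered share was 14.3% ± 8.32 (SD, n = 3) after the first transfer and 10.2% ± 1.97 (SD, n = 3) after the second, a difference of -4.16 points within the spread of replicates (exact permutation test, two-sided, p = 0.7). Altered segments numbered 8.33 ± 4.93 and 15.8 ± 9.17 per library (exact permutation p = 0.3), and this order turned when neighbouring altered segments were joined (difference -0.833). Without first transfer BR3 the difference in share was 0.539 points. Among the 4 libraries whose deposited names share a prefix, BR1 and BR2 of each transfer, it was 0.636 points (exact permutation p = 0.67), that in segments was 15.5 (exact permutation p = 0.33, the smallest that 2 against 2 allows, so it cannot pass), and the other libraries give no comparison within a prefix. Second transfer BR1 and BR2, with 19 and 23 altered segments, also had window SDs of 0.063 and 0.072 on autosomes without gains, against 0.031 and 0.033 from bin noise. In the other libraries these SDs were 0.035 to 0.048, against 0.029 to 0.034 from bin noise.

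The largest altered segment was most of a chromosome or a large part of it in every library. It was chromosome 2 from 22541733 to 182013224 in first transfer BR2 (log2 0.43) and BR3 (0.42), chromosome 16 from 3000001 to 98107768 in first transfer BR1 (0.28) and to 67445451 in second transfer BR1 (0.28). It was chromosome 15 from 3050001 to 38734237 in second transfer BR2 (0.48), and chromosome 6 from 41542779 to 149586546 in second transfer BR3 and BR4 (both 0.54). Of the 10 most extreme segments outside the antigen receptor loci, 8 were on the Y chromosome of first transfer BR2 and BR3 and second transfer BR1 and BR2, at -14.85 to -11.63. The other 2 were in first transfer BR2, on the X chromosome from 163217195 to 163367314 (-3.72) and on chromosome 13 from 65704572 to 66504363 (-2.08). First transfer BR3 and second transfer BR1 and BR2 held 1.82 to 1.87 copies of X, close to those of XX cells. Their Y values therefore do not by themselves show a loss. First transfer BR2 held 1.00 copy of X.

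Between transfers, chromosomes 2 and 11 separated the groups in order though not by the test. The mean log2 of chromosome 2 was 0.34 ± 0.14 (SD, n = 3) after the first transfer and 0.074 ± 0.055 (SD, n = 3) after the second, with every first transfer sample above every second transfer sample. Chromosome 11 was at -0.0045 ± 0.0020 (SD, n = 3) and 0.016 ± 0.018 (SD, n = 3), with every second transfer sample above every first transfer sample. This order on chromosome 11 lies within error. It was at -0.0028 in first transfer BR1 and -0.0015 and -0.0025 in second transfer BR3 and BR4 (SE over 5 Mb blocks 0.0037 to 0.0043). Second transfer BR1 and BR2 were at 0.035 and 0.016. For chromosomes 2 and 11 the exact permutation p was 0.1, the smallest that 3 against 3 allows, and 0.71 after adjustment over 19 autosomes. No window passed limma's test between transfers (0 of 2403, with 275 at an unadjusted p under 0.05). Without first transfer BR1, 171 windows passed, all on chromosome 2 and all lower after the second transfer, with a median difference of -0.35. Within the libraries that share a name prefix 0 windows passed limma's test, with 387 at an unadjusted p under 0.05.

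The third question was which genes of 6 lists fixed in advance lay in the changed segments. Of 154 list genes, 50 were in gained segments in at least 2 libraries and 0 in lost ones. With second transfer BR3 and BR4 counted once, 34 were gained in at least 2 samples. On chromosome 17, gained in 7 of 7 libraries, lay the cyclin gene Ccnd3 (bin log2 0.64 ± 0.077), Uhrf1, which recruits DNA methylation maintenance (0.65 ± 0.067), and Vav1, a T cell receptor signalling factor (0.52 ± 0.077). The Notch receptor gene Notch3 (0.64 ± 0.14), the cell cycle inhibitor gene Cdkn1a (0.49 ± 0.15) and the mismatch repair gene Msh6 (0.57 ± 0.076) also lay there. These genes passed limma over 20541 genes (adjusted p at most 0.00016, SD over n = 6) and did so whichever library was left out.

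On chromosome 15, gained in 3 libraries, Myc (0.41 ± 0.25, limma adjusted p = 0.011, n = 6) passed in every leave-one-out fit. These libraries might share an origin, and the calls on this chromosome count them as independent. Chromosome 15 as a whole was at 0.27 over the same 6 samples and passed in 3 of 7 leave-one-out fits. The value of Myc rests on the few bins over the gene, so its call is no firmer than that of the chromosome. The cohesin gene Rad21 (0.37 ± 0.25, 0.016) and the IL-7 receptor gene Il7r (0.34 ± 0.24, 0.021) lost their limma call without second transfer BR1 or BR2 (adjusted p up to 0.061 and 0.072). Xrcc6, of non-homologous end joining (0.36 ± 0.29, limma adjusted p = 0.030), lost it without first transfer BR2 or BR3 or second transfer BR1 or BR2 (up to 0.096), and the separase gene Espl1 did not pass (0.28 ± 0.29, 0.073). On chromosome 16, also gained in 3 libraries, Runx1 passed narrowly (0.26 ± 0.23, limma adjusted p = 0.046, and up to 0.13 with a library left out, lost without first transfer BR1, BR2 or BR3 or second transfer BR1 or BR2), while Bcl6 (0.25 ± 0.23, 0.052) and Prkdc (0.18 ± 0.20, 0.11) did not.

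In gained segments of 2 first transfer libraries on chromosome 2 lay B2m, of antigen presentation (0.26 ± 0.11, limma adjusted p = 0.0047), the spindle checkpoint gene Bub1 (0.30 ± 0.16, 0.0072), Prkcq (0.28 ± 0.16, 0.011) and the survival gene Bcl2l1 (0.25 ± 0.15, 0.015), which passed in every leave-one-out fit. Asxl1 (0.25 ± 0.15, limma adjusted p = 0.018) lost its call without first transfer BR2 or BR3 or second transfer BR1 (up to 0.059), and Il2ra (0.23 ± 0.22, 0.060) and Gata3 (0.24 ± 0.27, 0.090) did not pass. In gained segments of second transfer BR3 and BR4 on chromosome 6 lay Klrb1c, Cdkn1b and Etv6, which are thus gained in 1 sample and did not pass over the 6 samples (limma adjusted p = 0.31, 0.79 and 0.32). Each value rests on the few bins over a gene, and genes on 1 chromosome are not independent. Chromosome 2 as a whole was at 0.21 over the 6 samples and passed in 2 of 7 leave-one-out fits. Calls on its genes that passed in every such fit are therefore no firmer than that of the chromosome.

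Of all 20541 genes, 3084 were higher and 486 lower in limma's test, and the list counts were not tested against these shares. By list, 4 of 33 measured T cell tumour suppressors were higher in limma's test over all genes (Cdkn1a, B2m, Runx1 and Asxl1), and 3 adjusted over the list alone. Of 44 T cell oncogenes, 10 were higher and 2 lower (Mycn at -0.18 ± 0.13 and Ccnd1 at -0.20 ± 0.15), and 14 and 2 adjusted over the list alone. The 2 lower calls rest on the few bins over the genes, since neither lay in a lost segment. Segments over Ccnd1 were at -0.012 to -0.0020, and those over Mycn at -0.15 in second transfer BR2 and -0.012 to -0.0052 in the other libraries. Of 29 DNA repair genes 7 were higher and 7 adjusted over the list alone, and of 19 chromosome segregation genes 2 (Bub1 and Rad21) and 2. Of 11 DNA methylation genes 1 was higher (Uhrf1) and 3 adjusted over the list alone, and of 21 T cell identity genes 3 (Cd4, Cd2 and Cd44) and 3. Cd2 lay in a gained segment in 0 libraries, so its call rests on the few bins over the gene. The bin over Cd4 stood above its own flanks in 7 of 7 libraries, by 1.06 ± 0.13. Members named here outside the fixed rule were chosen after their values were seen.

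All 6 lists had a mean log2 above 0 in 6 of 6 samples, from 0.078 ± 0.044 (T cell identity) to 0.13 ± 0.043 (DNA repair; SD, n = 6, exact sign-flip adjusted p = 0.031 for each). Genes in general were also above 0, at 0.073 on average, and no list stood apart from circular shifts of the gene profile. The lists lay at percentiles 67.5 (tumour suppressors), 94.3 (oncogenes), 93.6 (DNA repair), 71.4 (segregation), 75.3 (DNA methylation) and 56.8 (T cell identity), with rotation permutation p from 0.39 to 0.87 after adjustment.

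The fourth question was whether the libraries carried the same alterations. Of the autosomes, 12.0% were altered in the same direction in at least 3 of the 6 samples, against 2.48% on average in random rotations (permutation p = 0.0015) and 3.72% when whole chromosomes were shuffled (permutation p = 0.033, an alternative chosen after seeing the data). This share fell to 4.06% without first transfer BR3 (permutation p = 0.051) or second transfer BR1 (0.094), to 7.84% without second transfer BR2 and to 8.26% without first transfer BR1, and the p was at most 0.014 without any 1 of the libraries other than first transfer BR3 and second transfer BR1. Rotations treat the samples as independent, which is not known. First transfer BR3 and second transfer BR1 and BR2 also differed over receptor bins by only 0.851 to 0.910 times the flanking noise, so these p-values do not exclude that a common origin of these samples gives the sharing. In at least 2 samples 19.6% were altered, against 15.6% in rotations (permutation p = 0.17), and by whole chromosomes 19.4% against 19.9% when shuffled (permutation p = 0.52). The rotation p was 0.042, 0.014 and 0.049 without first transfer BR1, second transfer BR1 or second transfer BR2. It was 0.43 and 0.12 without first transfer BR2 or BR3, where the share was 12.1%. Window profiles of 15 pairs of samples correlated at a mean Pearson r of 0.615 (mean Spearman rho 0.572) across windows, which are not independent replicates. Unchanged libraries simulated with a shared reference gave 0.196, and the mean covariance was 0.0187 against 0.000186 simulated. Over 13 autosomes without gains, pairs of libraries already correlated at 0.29 to 0.75. Exceeding the simulated value therefore does not by itself show shared gains. Pairs within a transfer group exceeded pairs between groups by 0.034 (exact permutation test, one-sided, p = 0.3).

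Antigen receptor loci mark rearrangement in T and B cells. The core of Trb (chromosome 6 from 41193106 to 41542778) held 0.022, 0.093, 0.188 and 0.197 copies in first transfer BR2 and BR3 and second transfer BR1 and BR2. It held 1.07 in first transfer BR1 and 2.05 and 2.01 in second transfer BR3 and BR4, where the chromosome stood at 2.91, against 0.744 in the wild-type reference. The core of Tra/Trd (chromosome 14 from 53617736 to 54067637) held 0.314, 0.0080 and 0.0721 copies in first transfer BR1 to BR3 and 0.145, 0.177, 0.247 and 0.231 in second transfer BR1 to BR4, against 0.511 in the reference.

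Over whole loci none of the 6 passed the exact sign-flip test. Tra/Trd was at -1.12 ± 1.22, Trg at -0.13 ± 0.099 (both lower in 6 of 6) and Igh at 0.045 ± 0.023 (higher in 6 of 6; SD, n = 6, exact adjusted p = 0.063 for each). Trb was at -1.38 ± 2.39 (lower in 4 of 6, exact adjusted p = 0.23), Igk at 0.086 ± 0.22 (0.56) and Igl at 0.22 ± 0.21 (0.19). These means keep the value of the chromosome that holds the locus. Igk was at 0.51 and 0.53 in second transfer BR3 and BR4, where chromosome 6 was at 0.54, and at -0.023 to 0.041 in the other libraries. Igl was at 0.33, 0.54 and 0.31 in first transfer BR1 and BR3 and second transfer BR1, where chromosome 16 was at 0.28, 0.53 and 0.33. The size of the means of Tra/Trd and Trb leans on bins close to 0 copies (log2 below -8), which in first transfer BR2 were 6 of 8 core bins of Tra/Trd and 4 of 7 of Trb. In second transfer BR3 and BR4 they were 4 and 3 of 8 core bins of Tra/Trd. Without first transfer BR2 Tra/Trd was at -0.67 and Trb at -0.49, and as the log2 of the mean ratio, an alternative chosen after seeing the data, they were at -0.34 and -0.36. With unweighted medians Tra/Trd was at -0.16 (exact adjusted p = 0.38). With 7 libraries counted separately 3 loci passed (Tra/Trd, Trg and Igh, exact adjusted p = 0.031). Between transfers no locus passed the exact permutation test (adjusted p from 0.6 to 0.9).

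**Figure D2:**
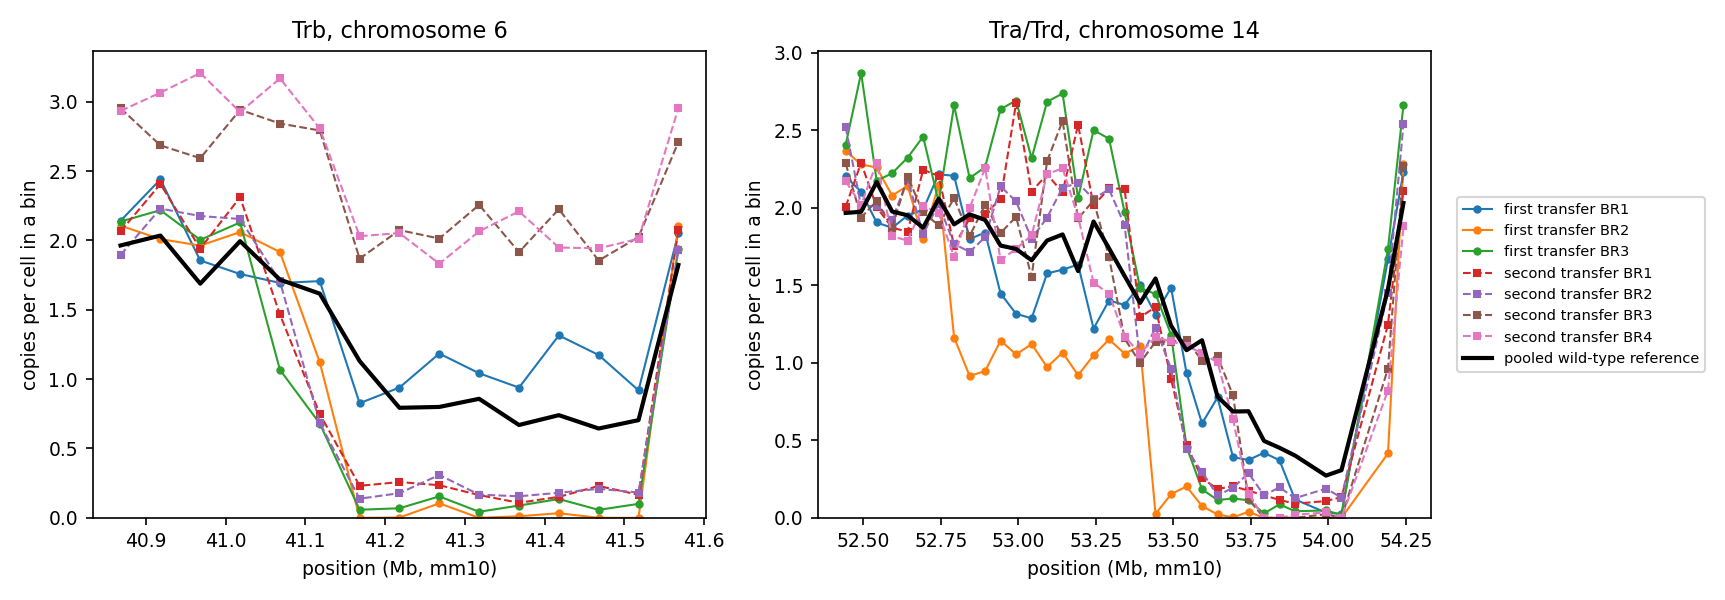
Copies per cell (vertical axis) of each bin along Trb and Tra/Trd (horizontal axis, position in Mb) in the 7 libraries and the pooled wild-type reference. In the core of Trb, first transfer BR2 and BR3 and second transfer BR1 and BR2 have mean copies of 0.022 to 0.197, and second transfer BR3 and BR4 have 2.05 and 2.01.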

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

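All tests in this part were chosen after the result was seen, and the bound that keeps the test of a shared clone open was tightened after its value was known.

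The sex chromosomes lay outside the autosomal comparisons, and X or the proximal Y exceeded 1.5 times the pooled wild-type reference (1.13 and 0.943 copies) in the following 5 libraries. First transfer BR3, second transfer BR1 and second transfer BR2 carried 1.83, 1.87 and 1.82 copies of X per cell, with 0.0118 copies or fewer of the proximal Y. These are close to the copies of XX cells, set against a reference near 1 copy of each, so the ratio does not by itself show a gain. Second transfer BR3 and BR4 carried 1.93 and 1.91 copies of the proximal Y, with 1.01 copies of X in each. Of the others, first transfer BR1 had 1.00 copy of X and 0.986 of the proximal Y, and first transfer BR2 had 1.00 copy of X and 0.0108 of the proximal Y. Outliers within a group were not tested, since each group holds 3 samples.

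Second transfer BR3 and BR4 shared their Y gain, the gain of chromosome 6 and the Trb profile. A single set of reads deposited under both names is argued against, since bin residuals correlated at 0.274 and not near 1. Separate libraries of the same cells remain open, since the variance of their window differences was 1.00 times the bin noise, against 3.26 to 36.3 in the other 20 pairs. A shared T cell clone that expanded in both recipients may give the same profile, and the receptor bins differed by 0.916 times the flanking noise. That ratio was also at or below 1.5 in 4 of the other 20 pairs, 3 of them among first transfer BR3 and second transfer BR1 and BR2 (0.879, 0.910 and 0.851), which also share their X and Y copies and might share an origin, so these explanations cannot be told apart here.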

How the results depend on the processing

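The alternatives with 7 libraries counted separately, joined segments, a linear receptor scale and shuffled chromosomes were chosen after seeing the data, as was the count of other splits. Windows departing from the reference numbered 334, against 529 with 7 libraries separate, 531 recentred on the mode and 92 with 5 Mb windows, where fewer windows are tested; the cause of the rise on recentring was not tested. Autosomes past the threshold numbered 11, against 0 with the exact sign-flip test, whose smallest p is 0.03125, and 3 with unweighted medians, where the cause was not tested. Receptor loci went from 0 to 3 with 7 libraries separate, where smaller p-values become possible. The difference in altered share (-4.16 points) turned to 0.636 in the 4 libraries that share a name prefix. These do not include first transfer BR3, and leaving out that library alone gave 0.539. The difference in altered segments (7.5) turned to -0.833 with neighbours joined. In second transfer BR1 and BR2 the gains of chromosomes 15 and 17 were cut into many adjoining segments, which joining merges. Why these libraries were cut more finely was not tested.

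Leaving out each library in turn gave 121 to 350 windows against the reference, 0 to 171 between transfers, 7 to 11 autosomes, 0 receptor loci, 0 Tet genes and 12.1% to 19.6% of the autosomes altered in at least 2 samples. The difference in share ranged from -7.37 to 0.539 points (above 0 without first transfer BR3) and that in segments from 3.92 to 10.3. Gene lists past the test ranged from 0 to 6, since 5 samples allow no p under 0.0625. Tet2 before its chromosome's mean is taken off, at -0.0078, ranged from -0.029 to 0.0052, the latter without second transfer BR4.

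With the replicate number as a block, the difference in share was -4.16 points (exact p = 0.75), that in segments 7.67 (exact p = 0.5), and 0 windows passed. The numbers do not pair the samples, since deviations of same-numbered libraries correlated at -0.297, -0.201 and -0.497, and no library correlated best with its own number.

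The 6 samples make 10 splits, too few for a share under 0.05; the real split gave 0 windows, so all 10 gave as many, and the highest other gave 61. That split sets first transfer BR1 and BR2 and the averaged second transfer BR3 and BR4 against first transfer BR3 and second transfer BR1 and BR2. The latter libraries share their X and Y copies and receptor bins and might share an origin. Whether this or another structure of the samples gives the count was not tested. In the simulation, which left out the spread between samples that gained chromosomes add, 23.9% of differences of 0.1 between transfers were recovered.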

Other observations

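The regions and tests in this part were chosen after the result was seen, except the test of gene density; the bound for the Cd4 copies was tightened after their values were known.

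Smaller regions lay below their flanks, most clearly in some libraries. A stretch of chromosome 4 from 132928831 to 134328439 with 40 protein-coding genes, among them Arid1a, a subunit of a chromatin remodelling complex, was below its flanks by a log2 of -0.74 ± 0.035 (SE over bins) in first transfer BR3. It was at -0.23 ± 0.035 in second transfer BR1 and -0.16 ± 0.026 in first transfer BR1, and at -0.012 to 0.043 in the other libraries. Chromosome 1 from 171081495 to 172032307, which holds Sdhc, a subunit of succinate dehydrogenase, was at -0.36 ± 0.036 in first transfer BR1 and above its flanks in the other libraries. Chromosome 9 from 27766798 to 30317241, which holds the neural adhesion genes Opcml and Ntm, was at -0.19 ± 0.026 in first transfer BR3, -0.13 ± 0.022 in second transfer BR1 and -0.18 ± 0.027 in second transfer BR2. It was also lower in the rest, at -0.079 ± 0.020 in second transfer BR3 and -0.055 to -0.033 in the others (7 of 7 libraries, exact sign-flip p = 0.031, n = 6, unadjusted). First transfer BR3 and second transfer BR1 and BR2 also had the largest window SDs on autosomes without gains, at 0.048, 0.063 and 0.072. Whether the broad waves described below give the lower values of this region was not tested.

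Other regions lay more than 3 SE from their flanks in all 7 libraries. Chromosome 3 from 60365863 to 60815963, over Mbnl1, was at 0.67 ± 0.027 above its flanks (SD, n = 6), and chromosome 5 from 14912509 to 15757302, over Speer genes, at 1.06 ± 0.063. Chromosome 13 from 65704572 to 66504363 was at -1.93 ± 0.11 and chromosome 14 from 69264331 to 69664243, over Entpd4, at -0.97 ± 0.057 (exact sign-flip p = 0.031 for each, unadjusted). Chromosome 14 from 25902793 to 26298546, over Duxbl genes, was at -0.61 and -0.55 in second transfer BR3 and BR4 and at -1.61 to -1.23 in the other libraries. By contrast, chromosome 17 from 6314561 to 6565663, over Dynlt1b, was beyond 3 SE in 3 libraries, at 0.37 and 0.38 above its flanks in second transfer BR3 and BR4, 0.21 in first transfer BR1 and -0.13 to 0.0080 in the rest. Over the Speer genes the reference itself was at a log2 of 0.87. Mutant cells from before transfer were not among the samples. Regions that differ in all 7 libraries are therefore not shown to have changed after transfer.

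The bin over Cd4 (chromosome 6 from 124866795 to 124916781) was above its flanks in 7 of 7 libraries, by 1.06 ± 0.13 (SD, n = 6, exact sign-flip p = 0.031). Noise in a single bin is argued against, since the lowest excess was 6.35 bin SDs. Extra Cd4 sequence elsewhere in the genome, as in a transgene, may account for it, although the labels name none. The extra copies over the flank median were 2.50 and 2.77 in second transfer BR3 and BR4, which carry a gained chromosome 6, and 1.93 to 2.79 in the other libraries, while scaling with the chromosome would give 3.43. With an SD of 0.54 copies for a single bin this cannot be told apart from a repeat on chromosome 6 itself.

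Second transfer BR1 and BR2 showed broad waves along autosomes without gains, with window SDs of 0.063 and 0.072 against 0.031 and 0.033 from bin noise, and 0.035 to 0.048 in the other libraries against 0.029 to 0.034. GC content as the whole cause is argued against, since their wave profiles still correlated at 0.747 after it was removed, and at most 0.603 in the other 20 pairs. Low depth is also argued against, since 0 of these libraries had a bin spread above all others. A larger share of cells in DNA replication remains open, since the waves followed gene density, a stand-in for early replication, with a rho of at least 0.335 across windows. The rho was above 0 in all 7 libraries, from 0.084, so it is not specific to this pair, and other causes were not tested.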
